A study of Mus musculus with 6 samples.

How the data were processed

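The data are 6 Affymetrix Mouse Gene 1.0 ST arrays, each hybridised with biotin-labelled RNA from hand-dissected larger proximal airways, 3 from Scgb1a1-Cre control mice and 3 from mice with the same driver and floxed Foxp1 and Foxp4. The deposited values are log2 expression values, 1 per probe set and array, and the submitters' processing notes name oligo, RMA and limma. Their versions, and whether the arrays were normalised together, are not given in the sources used here. RMA corrects background, scales the arrays to a shared distribution and summarises probes, and it compresses differences of dim probe sets. Scanner files, detection calls and scan dates were not used here, so no probe set could be called above or below background and no batch could be tested. The labels number the samples of each group 1 to 3 and do not say that each came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical. No 2 arrays held identical values, and pairs differed across genes with an SD of at least 0.238 log2 units.

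The platform's probe annotation named exactly 1 gene for 21789 of 35556 rows, several genes for 1621 and listed none for 12146. Of the rows with 1 symbol, the gene identifier of 21698 was found in the reference gene table, and 0 symbols needed updating. Where several rows named 1 gene, which was so for 999 genes, the row with the highest mean over the 6 arrays was used, leaving 19938 genes. Among the genes chosen by the naming rule given below, Ciart, Dnajc3, Etv5 and Hspb1 had a second row. Both rows of Ciart, Etv5 and Hspb1 differed in the same direction. Those of Dnajc3 had the same mean and the same difference, so they are no second measurement. Genes named outside that rule were not checked for further rows. The genome build of the array is not given in the sources used here, so no coordinates are printed. The mouse assembly GRCm38.p6 served only for the order of neighbouring genes.

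Mutant and control arrays were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the log2 values as deposited, with genotype as the only term, no filter and no intensity trend. The test was two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes with a threshold of 0.05. Fold changes are 2 to the power of the log2 difference of the group means, and standard errors are limma's moderated ones. For Foxp1, Foxp4 and Npy an exact permutation test was added, which cannot go below p = 0.1 with 3 arrays per group. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 measured genes. camera compares a list with all other genes, whereas fry, used as an alternative, tests whether a list's genes move one way on balance or, in its mixed form, in either direction. Members were counted past the threshold over all genes and adjusted over the list alone. Chad, Chat, Clca1, Egr2, Il25, Muc5ac, Pcsk1 and Scgb1a1 each stand in a pair of lists.

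The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were all members of the Foxp and neuropeptide Y lists; the 12 higher and 12 lower genes with the largest difference among those that passed with groups that did not overlap, leaving out predicted and unnamed transcripts, small RNAs and olfactory or vomeronasal receptors; and up to 4 members of each list by p, or up to 8 where they passed. As 6 genes passed as lower, that direction was filled up by smallest p from genes that differed by at least 1.5-fold. The gene families of the closing part, and the settings without controls 2 and 3 and without control 1 and mutant 2, were chosen after seeing the data. Alternatives were repeated quantile normalisation, median centring, leaving out the lowest 40% of genes by mean, the replicate number as a block, array weights, the mean of a gene's rows, leaving out each array in turn, an intensity trend, robust eBayes, all rows of the table, other thresholds, a plain per-gene t statistic, and camera with an estimated correlation or on ranks.

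The procedure was tested on simulated data for mutant against control with 3 arrays each and 19938 genes, drawn from the measured means and limma's spread per gene. Of 100 genes made to differ by 2-fold, 83% were called, and of 100 made to differ by 8-fold, 99% were called, with 13 calls among unchanged genes. Without simulated differences 0 genes and 0 lists were called, and a shift of 0.5 in the ciliated cell list was found. The simulated genes varied independently, which the measured ones do not. Their spread was limma's moderated one, which differs less between genes than the measured spread, so these shares may run high. Tables were joined in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.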

Results

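Gene expression was measured in the larger proximal airways of 9-week-old mice of mixed C57BL/6 and 129X1 background. The airways were dissected by hand from stained frozen lung sections, and each RNA sample was hybridised to 1 Affymetrix mouse gene array. There were 3 control arrays from mice with the Scgb1a1-Cre driver alone. The other 3 arrays came from mutants in which the same driver, active in club cells of the airway epithelium, acted on floxed Foxp1 and Foxp4, which encode forkhead transcription factors. The series also names lung resistance and compliance after methacholine, which were not analysed here. Each array gave 35556 log2 values, with array medians between 5.89 and 5.95 and Pearson correlations across the 19938 named genes between 0.972 and 0.993 for pairs of arrays. Control 1 correlated at a mean of 0.975 with the other controls and at 0.981 with the mutants. On the main axis of variation across genes (first principal component, 45.4% of the variance), control 1 (-11.3) lay with the mutants (-23.0 to -11.3). Controls 2 and 3 lay apart (38.4 and 29.4). The number of arrays limits the precision of every value.

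The targeted genes were examined first. Foxp1 (probe set 10546661) had a mean log2 value of 9.53 ± 0.10 (SD, n = 3) in control airways and 9.30 ± 0.05 in mutant airways. Foxp4 (probe set 10451613) stood at 8.91 ± 0.13 in controls and 8.22 ± 0.40 in mutants. Every mutant array lay below every control array for both genes. The log2 difference was -0.23 for Foxp1 (SE 0.085) and -0.69 for Foxp4 (SE 0.20), and neither passed limma's test after Benjamini-Hochberg adjustment (adjusted p = 0.444 and 0.339). An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 for each, the smallest value it can give. The probe sets cover whole transcripts, including exons outside the floxed part, and cells without Cre keep both genes, so these values check the labels only in part. Neither of the family members Foxp2 (log2 difference 0.25) and Foxp3 (-0.41) passed. Scgb1a1, whose promoter drives the Cre, was 0.25 higher in mutants on the log2 scale and did not pass either (adjusted p = 0.476).

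The series title names neuropeptide Y, and the comparison of its gene between mutant and control airways addressed that question. Npy (probe set 10538247) rose 33.1-fold in mutant airways, by 5.05 on the log2 scale (SE 0.35; limma adjusted p = 0.0067). The control arrays read 5.88, 5.92 and 6.08, and the mutant arrays read 11.4, 10.1 and 11.5. The exact permutation test again gave its smallest possible two-sided p of 0.1. Of the 12 measured genes in the fixed list of the neuropeptide Y system, only Npy passed, over all genes and adjusted over the list alone. None of its receptor genes passed: Npy1r averaged 6.22 in controls and 5.93 in mutants, and Npy5r averaged 4.51 and 4.61. The related peptide genes Pyy (log2 difference 0.18) and Ppy (0.08), the processing enzyme genes Pam (0.04), Pcsk1 (0.04) and Cpe (0.06), and Dpp4 (-0.14), whose product trims the peptide, did not pass. The list as a whole did not shift (median log2 fold change 0.04, camera adjusted p = 0.705). The call on Npy was lost without control 2 (adjusted p = 0.0581) and without control 3 (adjusted p = 0.0685). Single genes were not followed under the intensity trend, robust eBayes, all rows, other thresholds or the plain t statistic. Over the settings that followed them, the log2 difference of Npy stayed between 4.82 and 5.48. Where these kept several arrays per group, its limma adjusted p ranged from 0.000101 to 0.0814.

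**Figure D1:**
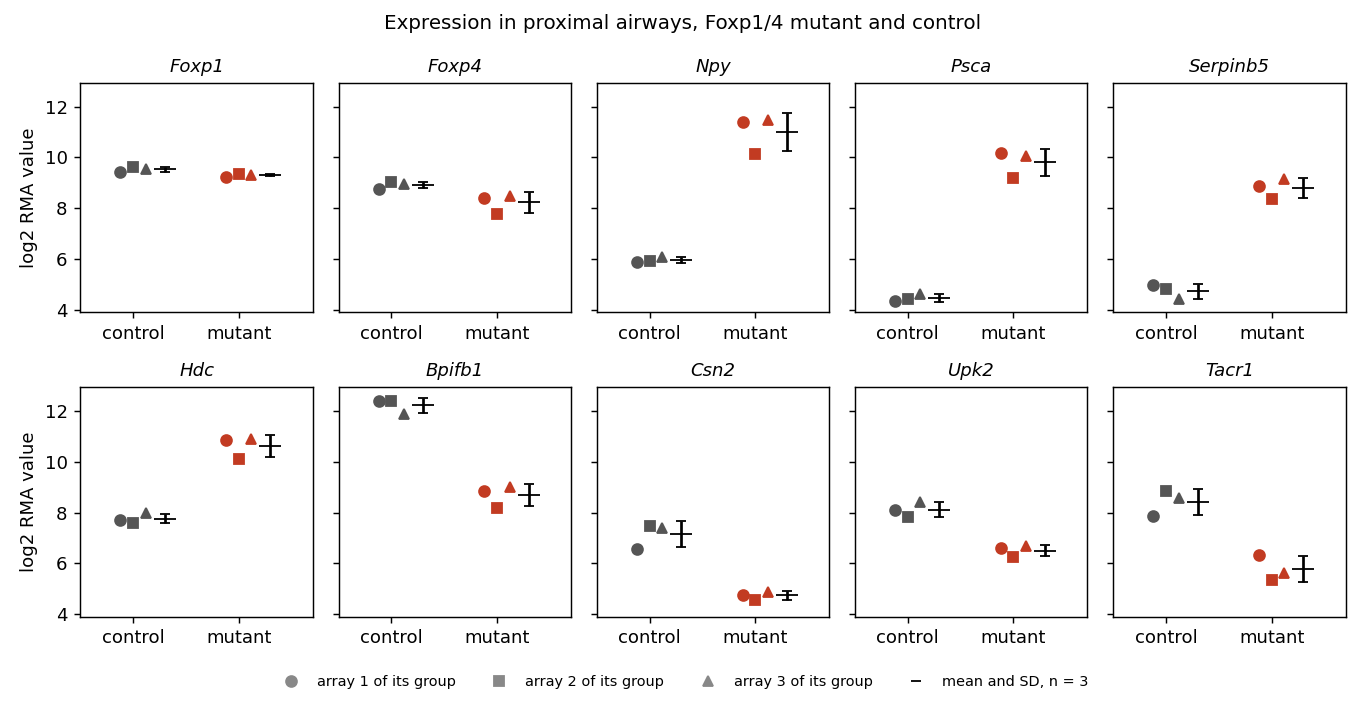
Log2 RMA values (y axis) of 10 genes on each of the 3 control (grey) and 3 mutant (red) arrays, with the group mean and SD (n = 3) as bars. Npy lies between 10.1 and 11.5 in mutants against 5.88 to 6.08 in controls, whereas Foxp1 and Foxp4 differ by 0.23 and 0.69; Foxp1, Foxp4 and Tacr1 did not pass limma's test.

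Across the transcriptome, mutant airways differed from controls mainly by genes with higher expression. Psca, which encodes a GPI-anchored surface protein, rose 41.0-fold as measured (log2 5.36, SE 0.26, adjusted p = 0.0025). Serpinb5, an epithelial serpin also called maspin, rose 16.8-fold (log2 4.07, SE 0.24). In the other direction Bpifb1, a secreted BPI fold protein of the airway lining, fell 11.8-fold, from a control mean of 12.2 to 8.68 (log2 difference -3.56, SE 0.25, adjusted p = 0.0067). In all, limma called 53 of 19938 genes at an adjusted p under 0.05, of which 47 were higher and 6 lower in mutants. All 53 had groups that did not overlap, as did 15.0% of all genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2007 genes, against 997 expected by chance. The count moved when single arrays were left out, to 388 without control 1, 9 without control 2, 10 without control 3, 16 without mutant 1, 24 without mutant 2 and 15 without mutant 3. Without control 1 most of the calls, 271 of 388, were of lower expression.

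Several of the genes that rose encode enzymes. Enpp6, a choline-specific phosphodiesterase, rose 8.76-fold, and Cela2a, an elastase best known from the pancreas, rose 7.78-fold. Hdc, the enzyme that makes histamine, rose 7.30-fold from a control mean of 7.76 to 10.6 (SE 0.23 on the log2 scale, adjusted p = 0.0129). Gucy1b2, a subunit of soluble guanylate cyclase, rose 7.17-fold, the ectonucleotidase Entpd8 rose 6.85-fold and Cpn1, the catalytic subunit of carboxypeptidase N, rose 6.05-fold. Vsig1, an adhesion molecule known from gastric epithelium, rose 5.50-fold, Clec12a, an inhibitory lectin receptor of myeloid cells, rose 4.91-fold, and the kinase gene Cdkl1 rose 4.67-fold. Their limma adjusted p ranged from 0.0037 for Enpp6 to 0.0226 for Gucy1b2. Control means of Psca (4.46), Gucy1b2 (4.50), Serpinb5 (4.73) and Vsig1 (4.85) lay close to the lower quartile of the arrays (4.42 to 4.50), and no probe set could be called above background, so folds against them are as measured and set no order. At least a 2-fold difference was reached by 36 of the genes that rose and 5 of those that fell.

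The genes that fell, besides Bpifb1, were Csn2, which encodes beta-casein (5.36-fold, adjusted p = 0.0246), the calpain protease gene Capn13 (3.63-fold), the glutathione transferase gene Gstm6 (3.28-fold), the uroplakin gene Upk2 (3.06-fold) and Pdzk1ip1, a small membrane protein (1.81-fold). The mutant mean of Csn2 (4.73) lay close to the lower quartile of the arrays, so its fold is as measured. Among genes that did not pass, 6 were taken by smallest p. These had groups that did not overlap and means that differed by at least 1.5-fold. Tacr1, the receptor for substance P, had the smallest p of these, with a mean of 8.42 ± 0.50 (SD) in controls and 5.76 ± 0.52 in mutants (log2 difference -2.66, SE 0.33, adjusted p = 0.0519). It passed in 5 of the other settings that followed single genes. Where these kept several arrays per group, its adjusted p ranged from 0.0043 to 0.242, and without control 1 it was 0.0165. Slc23a1, a vitamin C transporter, had a log2 difference of -1.13, Pcp4l1 of -1.29, Ebpl of -0.80, Itih2 of -1.20 and Aass, an enzyme of lysine breakdown, of -0.66. Of the 18 genes named so far that passed and had been ranked by size, 13 no longer passed without control 2, 13 without control 3, 10 without mutant 1, 8 without mutant 2 and 11 without mutant 3, while none changed direction.

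**Figure D2:**
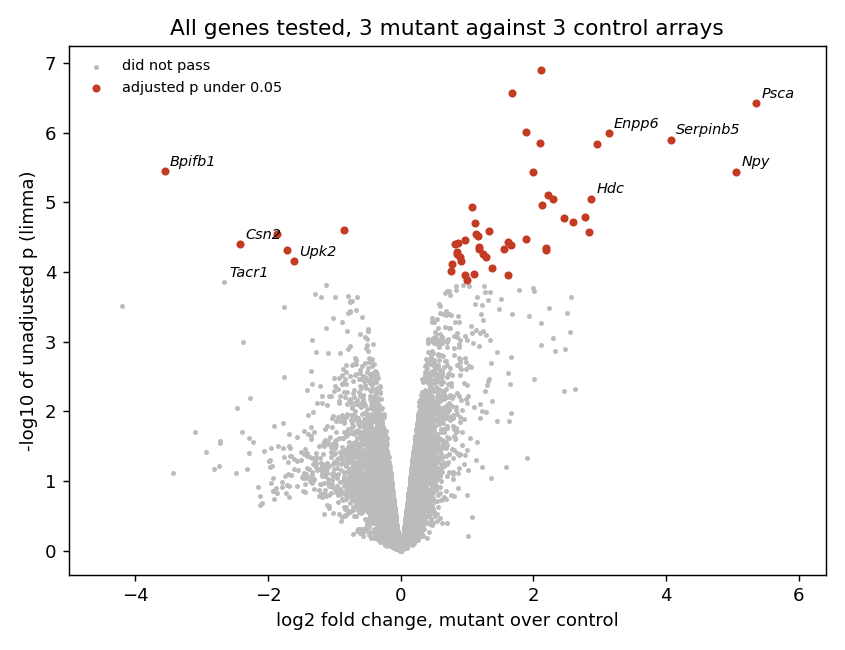
Log2 fold change of mutant over control (x axis) against the -log10 of limma's unadjusted p (y axis) for all 19938 genes, with the 53 genes past an adjusted p of 0.05 in red. Most red points, 47, lie to the right, among them Psca and Npy, and 6, among them Bpifb1, lie to the left; Tacr1 is named although it did not pass.

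Among the airway epithelial lists, secretory cells showed single genes that differed rather than a shift of the list. In the list of goblet cell and mucus genes, 1 of 22 measured members passed over all genes, Bpifb1. Adjusted over the list alone 4 passed: the mucin gene Muc5b (log2 difference 0.76), Agr2 (1.33), which acts in mucin folding, and the trefoil factor gene Tff2 (0.60) were higher, and Bpifb1 lower. This list had a median of 0.08, a mean of -0.07 and a test direction of higher (camera adjusted p = 0.750). Of 22 club cell genes, Upk3a rose over all genes (2.36-fold, adjusted p = 0.0264) and Gabrp, a GABA receptor subunit (0.52), joined it adjusted over the list alone; the list's median was 0.09 (camera adjusted p = 0.314). Upk3a no longer passed without control 2 (adjusted p = 0.0992), control 3 (0.129), mutant 1 (0.104), mutant 2 (0.0906) or mutant 3 (0.163). Over the settings that followed single genes and kept several arrays per group, its adjusted p ranged from 0.0071 to 0.163. Median log2 fold changes were -0.06 for ciliated cells, 0.25 for basal cells and -0.02 for neuroendocrine cells, and no member of these lists passed. As lists, basal cells did not pass as planned (camera adjusted p = 0.0928) but did on all 6 arrays with array weights (median 0.38, adjusted p = 0.0063) and with camera on ranks (adjusted p = 0.0474). They also passed without control 1 (median 0.43) and without mutant 2 (0.32), goblet cells without mutant 2 (0.25), and ciliated cells in opposite directions without mutant 2 (0.13) and without mutant 3 (-0.21). The tuft cell and ionocyte list had a median of 0.04, a mean of 0.01 and a test direction of lower, also without a called member. Ghrl, the ghrelin gene, was the only member of the list of other neuropeptides and peptide hormones to pass adjusted over the list alone (log2 difference 1.14), and that list had a median of 0.02.

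Alveolar type 2 genes were higher in mutants as a list, with a median log2 fold change of 0.30 over 12 genes (camera adjusted p = 0.0011 with a preset correlation of 0.01). With an estimated correlation it did not pass (adjusted p = 0.921, unadjusted p = 0.0279), nor without control 1 and mutant 2, a setting added after seeing the data (adjusted p = 0.0724). No member passed over all genes, and adjusted over the list alone the surfactant protein gene Sftpa1 (log2 difference 0.40), the lysozyme gene Lyz1 (0.88) and the transcription factor gene Etv5 (0.73) did. The alveolar type 1 list had a median of 0.19 and did not pass (camera adjusted p = 0.0983), but did without control 1 (median 0.34) and without mutant 3 (0.33).

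The series concerns airway constriction, and the fixed lists on that question did not pass camera on all arrays. With array weights they did not pass either (camera adjusted p = 0.357 for smooth muscle and 0.770 for bronchoconstriction). The smooth muscle contractile apparatus had a median log2 fold change of 0.02, a mean of -0.02 and a test direction of lower over 20 genes (camera adjusted p = 0.792). Bronchoconstriction receptors and signalling had a median of -0.01 over 25 genes, and its member Chrm3, the muscarinic receptor of airway smooth muscle, averaged 6.38 in controls and 5.58 in mutants without passing (adjusted p = 0.482). No member of either list passed, over all genes or adjusted over the list alone. The smooth muscle list passed in opposite directions in both settings chosen after seeing the data, with a median of -0.34 without controls 2 and 3 and 0.24 without control 1 and mutant 2, and the bronchoconstriction list passed without controls 2 and 3 (-0.15).

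Type 2 inflammation genes had a median log2 fold change of 0.13, with 20 of 26 members above 0, and did not pass (camera adjusted p = 0.0714), but did without control 2 (median 0.12), without mutant 1 (0.07) and without mutant 3 (0.13). Retnla, a protein of alternatively activated macrophages, passed adjusted over the list alone (log2 difference 1.20), and the eosinophil chemokine gene Ccl11 stood at 1.30 without passing (adjusted p = 0.226). Interferon response genes were higher as a list (median 0.27, camera adjusted p = 0.0200; adjusted p = 0.991 with an estimated correlation), with Oas1a (0.69) past the threshold adjusted over the list alone. That call was lost with array weights (median 0.19, adjusted p = 0.295), without control 1 (median 0.14, adjusted p = 0.315) and without mutant 1 (median 0.18, adjusted p = 0.156). In the mast cell and basophil list Hdc alone passed, and the mast cell protease genes Cma1 (log2 difference 0.15) and Tpsb2 (0.10) did not, with a list median of 0.04. Myeloid genes had a median of -0.07, with Cd14 lower adjusted over the list alone (-0.62). The mast cell list passed without control 1 (median 0.23) and the myeloid list with array weights (-0.35) and without mutant 2 (-0.36).

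Lymphoid genes were lower in mutants as lists. B and plasma cell genes had a median log2 fold change of -1.95 with all 14 members below 0 (camera adjusted p = 1.03e-06). T and NK cell genes had a median of -0.81 (adjusted p = 4.09e-06), and proliferation genes had a median of -0.42 with 18 of 19 members below 0 (adjusted p = 0.0012). With an estimated correlation the adjusted p values were 0.987, 0.987 and 0.991, and no single member of these lists passed, over all genes or adjusted over the list alone. The arrays of each group were far apart. The mean of the B and plasma cell genes was 6.44, 9.37 and 9.22 in the control arrays and 5.83, 7.70 and 5.92 in the mutant arrays, so control 1 lay among the mutants. For T and NK cells the means were 6.24, 7.44 and 7.47 against 5.90, 6.59 and 5.93. Without controls 2 and 3 together, a setting chosen after seeing these values, the B and plasma cell median became 0.10, that of T and NK cells -0.09 and the proliferation median 0.42. The proliferation call was also lost without control 2 (median -0.11, adjusted p = 0.202) and without control 3 (median -0.19, adjusted p = 0.160), while without control 1 the median was -0.90.

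**Figure D3:**
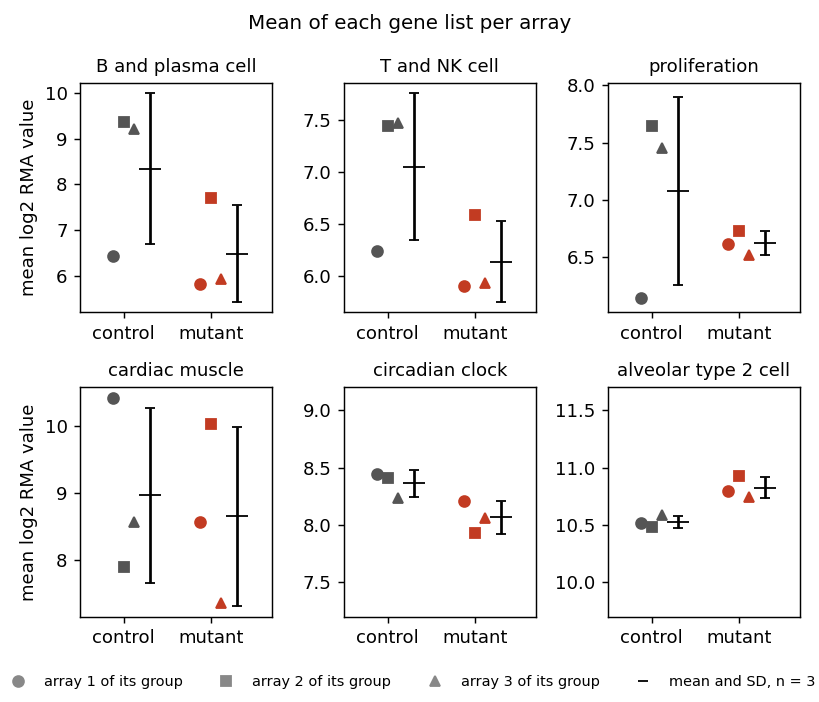
Mean log2 RMA value of the genes of 6 lists (y axes, each with its own range) on each control (grey) and mutant (red) array, with the group mean and SD (n = 3) as bars. B and plasma cell genes are high in controls 2 and 3 (9.37 and 9.22) and cardiac muscle genes in control 1 and mutant 2 (10.42 and 10.03). The alveolar type 2 list separates the groups (highest control 10.59, lowest mutant 10.75). The clock list does so only narrowly (lowest control 8.23, highest mutant 8.21).

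Circadian clock genes were lower as a list, with a median log2 fold change of -0.48 and 11 of 14 members below 0 (camera adjusted p = 0.0012; adjusted p = 0.948 with an estimated correlation). Adjusted over the list alone, Ciart (log2 difference -0.77), Bhlhe41 (-0.68) and Per3 (-0.73), which act against the activators of the clock or follow them, were lower, and the activator gene Clock (0.58) was higher. None passed over all genes. The list no longer passed without control 1 and mutant 2, a setting chosen after seeing the data (median -0.18, adjusted p = 0.0806).

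The remaining lists cover tissues that a dissected airway can carry, stress responses and sex-linked genes. None of those tested passed camera on all 6 arrays weighted equally. Cardiac muscle genes, known also from the pulmonary vein wall, had a median log2 fold change of -0.19 but differed widely within groups, with array means of 10.4, 7.90 and 8.58 in controls and 8.57, 10.03 and 7.36 in mutants. Adipocyte genes (median -0.12) followed the same arrays, with means of 9.73, 7.67 and 8.19 against 8.33, 9.02 and 7.97. The adipocyte median turned to 0.53 without control 1 and then passed, and the cardiac list passed with array weights (-0.48), without control 2 (-0.74) and without mutant 2 (-0.93). Endothelial genes passed without mutant 3 (0.15). Without controls 2 and 3, the endothelial median turned to -0.31 and the cartilage median was -0.34. Medians were 0.17 for fibroblasts and extracellular matrix, 0.03 for endothelial cells, -0.03 for cartilage, 0.09 for skeletal muscle, -0.01 for neurons and -0.15 for mesothelium, where Msln, the mesothelin gene, was lower adjusted over the list alone (log2 difference -2.38). Schwann cell genes had a median of -0.01, a mean of -0.06 and a test direction of higher. Foregut genes outside the lung had a median of 0.03, a mean of -0.05 and a test direction of higher, with Krt4 higher adjusted over the list alone (0.58). The unfolded protein response had a median of 0.03, and immediate early and heat shock genes had a median of -0.02, a mean of 0.03 and a test direction of higher. Over the 33 lists tested, 6 passed with the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05. The number passing was 11 without mutant 2 and 10 without mutant 3. The red blood cell list (median -0.06) and the sex-linked list (median 0.32) had 4 measured genes each and were not tested; the Y-linked gene Eif2s3y averaged 8.47 in controls and 8.67 in mutants, and Xist 4.33 and 4.73.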

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

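The test in this part was planned. Rows of the array without a single gene name entered no comparison above. Of these 13767 rows, 6 passed limma's adjusted p of 0.05 when all rows of the table were tested, 4 higher and 2 lower in mutants, and the 4 drew attention as a signal above the control arrays in data not otherwise reported on. The largest difference was a log2 change of -3.85 at probe set 10341070 (control mean 8.86, mutant mean 5.01, adjusted p = 0.0171), and the largest increase was 1.32 at probe set 10344157 (adjusted p = 0.0476). What these rows measure, and whether it is a transcript, was not analysed here.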

How the results depend on the processing

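The count of 53 genes stayed within 1.5 times under repeated quantile normalisation (54), median centring (56), leaving out the lowest 40% of genes (67), the mean of a gene's rows (52), robust eBayes (52), all rows (54) and a least difference of 1.5-fold (53). It became 291 with array weights, 82 with an intensity trend and 318 at an unadjusted p under 0.01 with a 1.5-fold difference. limma gave 0 without controls 2 and 3 (1542 genes at an unadjusted p under 0.05), where control 1 alone stands for its group and is assumed to vary like the mutants, and the plain t statistic also gave 0 (1679 unadjusted). Without control 1 and mutant 2 it was 963, of which 643 were lower. Both settings that leave out 2 arrays were chosen after seeing the data. Leaving out 1 array gave 9 to 388 genes. Apart from fewer samples, the cause of these moves was not tested.

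The labels do not say whether equal numbers in both groups mark related samples, and the values cannot decide it with so few arrays. Deviations from the group means correlated at 0.136, -0.0907 and -0.0398 between arrays of the same number, and not every array correlated best with its own number. With the replicate block limma called 0 genes (1945 at an unadjusted p under 0.05), all 18 size-ranked genes no longer passed, and Npy had a log2 difference of 5.05 with an adjusted p of 0.0814. The number of lists was 7, with basal cells added (adjusted p = 0.0234).

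Npy kept its direction in every setting that followed single genes, with a log2 difference of 5.13 without controls 2 and 3. The plain t statistic called 0 genes, so Npy did not pass there. Leaving out single arrays gave 4.82 to 5.48. Foxp1 kept its direction and did not pass in any setting that followed single genes. Foxp4 passed in 1 setting, without control 1 and mutant 2, at a log2 difference of -0.53. Foxp2 had a lowest limma adjusted p of 0.0351, and its log2 difference ran from -0.135 to 0.578, so its direction was not kept. Over 252 values of the 18 size-ranked genes under the other settings, 161 kept direction and call, 91 no longer passed and 0 changed direction.

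The number of lists, 6, became 0 with an estimated correlation, 0 with fry's directional p (6 lists at an unadjusted p under 0.05), 10 with fry's mixed p, 16 without controls 2 and 3, and 5 to 11 when single arrays were left out. Lists whose test turned direction and passed on either side were, as medians, smooth muscle without control 1 and mutant 2 (0.24), and without controls 2 and 3 the B and plasma cell (0.10), endothelial (-0.31) and proliferation lists (0.42). Leaving out single arrays, the ciliated median ran from -0.21 to 0.13 (without mutant 2) and the adipocyte median from -0.57 to 0.53 (without control 1), each turned and called at its upper end. With array weights the medians of alveolar type 2 (0.19), clock (-0.29) and proliferation genes (-0.70) moved by over 1.5 times and still passed. Single lists lost a call 25 times and gained one 41 times. Turns of direction that were called on neither side, 76 for lists and 62 for genes, are counted here as no reversal, a choice made after seeing them. No detection calls were used, so the level at which dim probe sets stop measuring RNA stays unknown.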

Other observations

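The tests of this part were chosen after the results were seen, except those of the other splits of the arrays and of the neighbours of Foxp1 and Foxp4. Gene families were grouped by symbol around genes already seen to differ, and some of their members also stand in the fixed lists. The families are therefore described by values, with adjusted p over all genes. Uroplakins, membrane proteins of urothelium and of some airway cells, moved apart: of 6 measured, Upk3a rose 2.36-fold and Upk2 fell 3.06-fold. The uroplakin gene Upk1b was 2.23-fold higher without passing (limma adjusted p = 0.429). Of 3 epithelial sodium channel subunits, Scnn1b and Scnn1g were 1.86-fold and 1.85-fold higher without passing (limma adjusted p = 0.172 and 0.122). Of 19 glutathione S-transferases, Gstm6 fell 3.28-fold, and Gstk1 had a log2 difference of -0.61 without passing (adjusted p = 0.230). Of 14 BPI fold proteins, Bpifb1 fell, and of 24 clade B serpins, Serpinb5 rose, while Serpinb10 stood at 2.02 without passing (adjusted p = 0.0581). All these directions held under both other scalings, which moved the values little and so test them little.

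Among the family genes named in this part, the largest difference that did not pass was that of a CC chemokine. Ccl20, an epithelial chemokine that attracts cells with the receptor Ccr6, was 18.3-fold lower in mutants (log2 difference -4.19, SE 0.60, adjusted p = 0.0723). Over the other settings the log2 difference ran from -4.92, without control 1, to -2.73, and the adjusted p from 0.000729 to 0.312, so it passed in some of them. Control arrays read 8.35, 10.9 and 10.2, and mutant arrays read 5.82, 5.45 and 5.59. Of the other CC chemokines, Ccl11 had a log2 difference of 1.30 (adjusted p = 0.226), Ccl5 of -1.10 (adjusted p = 0.293) and Ccl25 of 0.46 (adjusted p = 0.216). Both other scalings moved these values little and kept their directions.

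Over the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many as 53 genes. The highest other split gave 37 genes and set controls 2 and 3 with mutant 2, the arrays with the highest B and plasma cell means, against the rest. With 10 splits no share under 5% can be reached.

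The genes higher in mutants, among them Npy and Psca, could come from the airway cells or from other tissue or sequence carried with the mutants. Nerve tissue as the whole cause would bring its abundant transcripts, but the neuron list had a median log2 fold change of -0.0081, and Stmn2, its brightest gene, averaged 8.06 in controls and 7.68 in mutants. For stomach or oesophagus tissue, foregut genes outside the lung had a median of 0.029. That list also holds genes of pancreas, liver and intestine, so its median cannot decide. As the whole cause, such tissue is argued against by Gkn1 (log2 difference 0.03), Pgc (-0.02) and Krt13 (-0.02), members picked for this check. On the other side, 17 of 25 members lay above 0, and Krt4 was higher adjusted over the list alone (0.58). The gastric gene Vsig1, outside the list, rose 5.50-fold, so a part from such tissue stays open. Sequence of the 129X1 strain next to the floxed alleles would place called genes beside them, but 0 of the 200 nearest measured genes (assembly GRCm38.p6, 50 on either side of each) passed, and 22 had an unadjusted p under 0.05, as did 10.1% of all genes. The called genes thus lay outside these neighbours. Linked 129X1 sequence farther along the same chromosomes was not tested and stays open. A response to the loss of Foxp1 and Foxp4 in the epithelium, other strain differences, and which cells express these genes stay open and untested.

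The lower lymphoid lists in mutants came with a wide spread between arrays of a group. The B and plasma cell means spanned 2.93 log2 units within controls, more than the 1.86 between the group means, and control 1 lay within the range of the mutants, which is consistent with lymphoid tissue in some airway pieces of either genotype. The B and plasma cell mean was not higher in every control than in every mutant, since control 1 lay below mutant 2 (difference -1.26). For Ccl20, lymphoid RNA as the only source is argued against, since control 1 exceeded the highest mutant by 2.54 (mutant SD 0.18), and mutant 2, with a higher B and plasma cell mean than control 1 (7.70 and 6.44), had the lowest Ccl20 (5.45 against 8.35); a part from lymphoid cells stays open. Whether the mutants differ in their number of lymphoid follicles was not tested.

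Clock genes separated the groups by arm. The mean of 12 repressor and output genes minus that of the 2 activators Arntl and Clock was 1.15 ± 0.33 (SD) in controls and 0.13 ± 0.30 in mutants, and the lowest control lay 0.437 above the highest mutant. Lymphoid RNA in controls 2 and 3 as the cause is argued against: control 1, low in lymphoid genes, lay 1.09 above the highest mutant (mutant SD 0.30), and mutant 2, the mutant with the most, had the lowest contrast (-0.21). The clock list median was -0.45 without controls 2 and 3 and -0.18 without control 1 and mutant 2, the arrays high in cardiac muscle genes, whose part was not tested. Tissue taken at different times of day in the groups would give the same pattern and cannot be told apart from genotype, since no hour of collection was used here.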
